A study of Mus musculus with 12 samples.

How the data were processed

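The series holds 12 microarray profiles of primary epidermal keratinocytes from newborn FVB/n mice. Per the labels' protocols, cells were grown in EMEM with chelexed serum at 8% and 0.05 mM calcium chloride, received a v-Hras retrovirus on culture day 2 together with a lentivirus carrying scrambled, Ire1a or Xbp1 shRNA, and from 48 h after infection were selected in puromycin for 2 days. Control cultures received the scrambled shRNA lentivirus without v-Hras, were selected in the same way and had the same total time in culture. Each of the 4 groups has 3 biological replicates. RNA was isolated on day 5 after virus transduction per the growth protocol and on day 4 after lentiviral infection per the series text. Per the labels' protocols, RNA quality was assessed on an Agilent Bioanalyzer, cDNA was made from 100 ng of total RNA with the Ambion WT Expression kit, and it was fragmented and labelled with an Affymetrix kit for whole-transcript arrays. The number and sequences of the hairpins, the scan dates and the array batches are not given in the sources used here.

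The deposited values are in the unit intensity, on a linear scale, as the authors made them by RMA and with genome build mm10 per the submitters' processing notes; versions and settings are not given in the sources used here. RMA normally gives log2 values, and the plan made before the data were examined assumed them. The deposited values run from 1.57 to 11445 and are right-skewed, so log2 was taken before any test. That the linear scale holds RMA values turned back from log2 is an inference from the values. The table has 35145 entries, and 1352 of them held no value on any array, which left 33793 probe sets. Of these, 23521 carried exactly 1 gene symbol, 1814 several and 8458 none. Symbols were paired with the mouse RefSeq annotation of GRCm38.p6, which placed 23328 of the single-symbol probe sets. For each gene the single-symbol probe set with the highest mean over all arrays was kept, which gave 22180 genes, 1082 of which had more than 1 probe set. Genes without a single-symbol probe set, Hras and Krt5 among them, were not analysed here as genes. Of 727 symbols in the fixed lists 678 were measured.

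Array depth has no count; median intensity per array was 20.3 to 21.8. The SD of the log2 difference between replicate arrays was 0.28 to 0.373, between 0.151% and 0.326% of values were identical between replicates, and no pair of arrays was a copy. The mean correlation of an array with the others of its group was 0.987 to 0.993, lowest in the control group. The median standard error of a difference between groups was 0.129 on the log2 scale.

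Groups came from the sample titles and labels. Limma 3.58.1 in R 4.3.3 fitted 4 group means to all 12 arrays (8 residual degrees of freedom and 3.24 prior degrees of freedom), with Benjamini-Hochberg adjustment over all genes for each comparison and a threshold of 0.05. The comparisons were v-Hras against control, Ire1a shRNA against scrambled shRNA and Xbp1 shRNA against scrambled shRNA in v-Hras cells, Ire1a against Xbp1 shRNA, and each knockdown group against control. Standard deviations printed with means are those of the 3 arrays, and standard errors are limma's. Camera, from limma, tested 33 fixed lists against all other genes in the first 4 comparisons with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over all lists and comparisons together. Of these lists 27 are pathways or gene classes and 6 are marker sets of cell types that a newborn epidermal isolate can hold. The lists were written from general knowledge and overlap in part. Camera ranks a list against all other genes, so a list can be called with few of its members called. Camera with a correlation estimated from each list's residuals, given as "with an estimated correlation", and fry were run as alternatives.

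Calls shared by a pair of effects were counted beside the product of the list sizes over the number of genes, and beside 20 simulations in which groups without any effect shared the scrambled arrays. Counts of list members adjusted over the list alone are given where they differ from those over all genes. Detection calls were not used here. The lowest array median, chosen after the data were seen, marks dim signal in the text. It was looked up for the largest rises and falls, the gene families and some single genes, and not for every list member. The procedure was tested on simulated data for the Ire1a comparison. With 200 of 22180 genes changed it recovered 26.9% of changes of 0.5, 86.6% of changes of 1 and 100% of changes of 2 on the log2 scale, with 17 unchanged genes called, and over 10 draws a mean of 5.89% of calls were false.

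Groups, comparisons, tests, lists, alternatives and the rule for named genes were set before the data were examined. For each of the first 4 comparisons the rule names Ern1, Xbp1 and Hras, the 10 largest rises and 10 largest falls among called genes whose values do not overlap between the groups (leaving out predicted genes, Rik clones and small RNA genes), from each list up to 2 called members with the largest rise and 2 with the largest fall, and always Id1, Cdkn2a, Cdkn2b, Cdkn1a, Dnajb9, Hspa5, Ddit3, Bloc1s1, Ccnd1, Mki67, Krt1, Krt10 and Krt14. Only the last set is named against control. Of the genes that the rule names, the text prints mainly those whose call held in every fit that left out 1 array. Against control, Cdkn2a in both knockdown groups and Bloc1s1 with Xbp1 shRNA, whose calls were lost in some of those fits, are not printed.

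The alternatives were a further quantile normalization, cyclic loess, centring each array on its median, leaving out the dimmest 40% of genes, all probe sets, the mean of a gene's probe sets, only the 6 arrays compared, a variance trend with robust estimation, array weights, a block for replicate number, at least a 2-fold difference, leaving out each array in turn, and, chosen after the data were seen, an offset of 16 added before log2. Probe sets without exactly 1 symbol were left out of the gene tests and lists. Python 3.11.15 with matplotlib 3.10.9 drew the figures.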

Results

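Gene expression was measured in 12 cultures of primary epidermal keratinocytes from newborn FVB/n mice, with 1 Affymetrix whole-transcript array per culture and 4 groups of 3 biological replicates. Control cultures carried a lentivirus with a scrambled short hairpin RNA (shRNA) and no oncogene. The other 3 groups received a retrovirus with v-Hras, an oncogenic viral form of the small GTPase gene Hras, together with a lentivirus that carried the scrambled shRNA, an shRNA against Ire1a or an shRNA against Xbp1. Ire1a (gene symbol Ern1) encodes a sensor of endoplasmic reticulum (ER) stress with kinase and RNase activity, and its RNase splices Xbp1 mRNA into the form that encodes the active transcription factor XBP1s. The growth protocol places RNA isolation on day 5 after virus transduction, and the series text places it on day 4 after lentiviral infection. Median intensity per array lay between 20.3 and 21.8, the 75th percentile between 79.8 and 86.0. The first principal component held 61% of the variance and parted the control arrays (-70.2 to -68.4) from all v-Hras arrays (15.0 to 28.0). The second held 11.8% and parted the Ire1a shRNA arrays (-31.1 to -28.1) from the Xbp1 shRNA arrays (14.5 to 18). With 3 arrays per group, the number of arrays limits the precision of every difference, whose median standard error was 0.13 on the log2 scale.

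The shRNA targets moved in the cultures labelled for them. Ern1 (chromosome 11, 106397620 to 106487796, GRCm38/mm10) had intensities of 47.9, 60.6 and 72.7 in the control arrays, 142, 143 and 141 with v-Hras and scrambled shRNA, 49.2, 60.7 and 46.8 with Ire1a shRNA, and 105, 111 and 137 with Xbp1 shRNA. Relative to v-Hras with scrambled shRNA (log2 mean 7.15 ± 0.01, SD, n = 3), Ern1 fell by 1.45 on the log2 scale with Ire1a shRNA (5.70 ± 0.20, n = 3; 95% interval -1.79 to -1.11, limma adjusted p = 0.000112). Its difference with Xbp1 shRNA was -0.29 (6.86 ± 0.20, n = 3, limma adjusted p = 0.437). Xbp1 (chromosome 11, 5520641 to 5525993) had intensities of 397, 430 and 364 in control arrays, 475, 493 and 470 with v-Hras and scrambled shRNA, 363, 364 and 427 with Ire1a shRNA, and 224, 216 and 235 with Xbp1 shRNA. It fell by 1.09 with Xbp1 shRNA (7.81 ± 0.06 against 8.90 ± 0.04, n = 3; 95% interval -1.29 to -0.89, limma adjusted p = 0.000226).

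Changes of Xbp1 itself outside its own knockdown were small. With Ire1a shRNA its difference was -0.32 (limma adjusted p = 0.0381). That call was lost without v-Hras scrambled replicate 1, 2 or 3 (0.0896, 0.12 and 0.086), Ire1a shRNA replicate 1 or 2 (0.134 and 0.133), or Xbp1 shRNA replicate 1 or 2 (0.0553 and 0.0504). It was also lost on centring each array on its median, with all probe sets, with only the 6 arrays compared and with a replicate block. Splicing of Xbp1 mRNA was not analysed here. Neither was Hras itself, since no probe set carried its symbol alone.

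**Figure D1:**
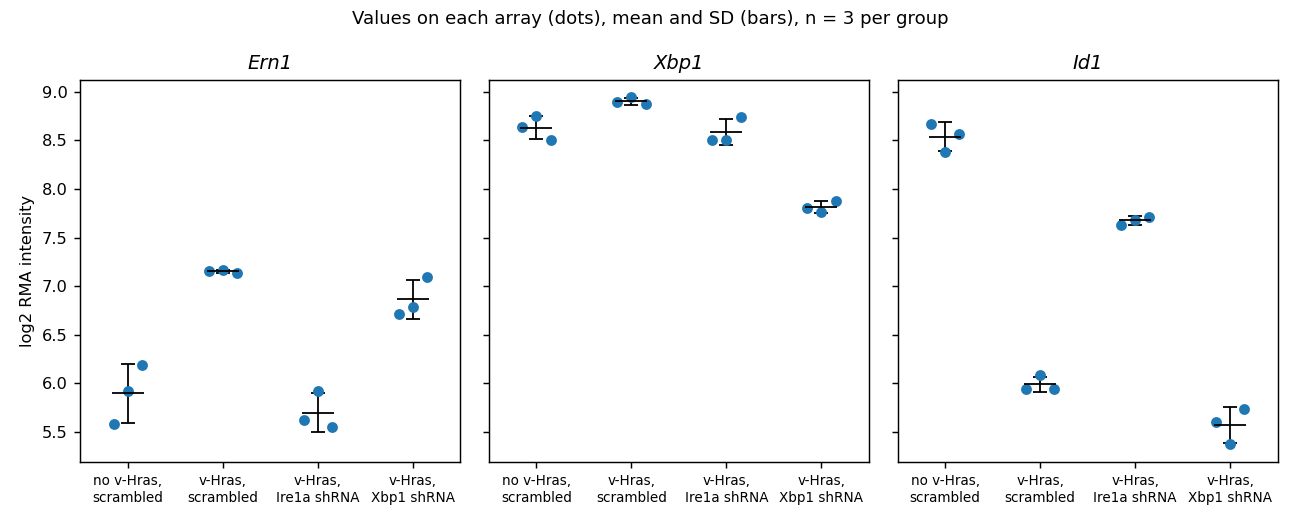
Log2 intensity of Ern1, Xbp1 and Id1 on each of the 12 arrays by group, with points for arrays and bars for the mean and SD of 3 arrays. Ern1 was at 7.15 with v-Hras and scrambled shRNA and 5.70 with Ire1a shRNA, Xbp1 was lowest with Xbp1 shRNA, and Id1 was 8.54 in controls, 5.99 with v-Hras and 7.68 with Ire1a shRNA.

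The comparison of v-Hras with control cultures, both with scrambled shRNA, asks what changed with the v-Hras retrovirus before any knockdown. The control titles name no empty retrovirus, so effects of the oncogene and of retroviral infection cannot be told apart here. Cell division genes, growth factors of the epidermal growth factor (EGF) family, amino acid response genes, lipid synthesis genes and ER chaperones rose together, while keratins of early differentiation, inhibitor of DNA binding (Id) genes and reported IRE1 cleavage substrates fell. The chemokine gene Ppbp rose from 3.90 ± 0.12 to 11.65 ± 0.09 (SD, n = 3; fitted log2 difference 7.75 ± 0.11, SE, limma adjusted p = 2.92e-12). Among the other 9 of the 10 largest fitted rises were the cornified envelope genes Sprr2e (6.63), Sprr2d (5.55) and Lce3b (5.46), the chemokine gene Cxcl3 (6.44) and the collagenase gene Mmp1b (5.88). Psca (6.12), Sprr2j-ps (5.87), Mal (5.40) and Gprc5a (5.38) completed them. The 10 largest fitted falls included the hair keratin gene Krt84 (-6.20; 4.25 ± 0.23 against 10.44 ± 0.06, n = 3, limma adjusted p = 1.31e-10), Clca3a2 (-6.14), Bex1 (-5.99), the monocarboxylate transporter gene Slc16a7 (-5.70) and the bone morphogenetic protein antagonist gene Sostdc1 (-5.33). The decoy interleukin 1 receptor gene Il1r2 (-5.29), Dapl1 (-4.82), Rgs5 (-4.79), Sema3d (-4.74) and the prostaglandin E receptor gene Ptger3 (-4.54) were the others. Detection calls were not used here. In 17 of these 20 genes, all except Mal, Bex1 and Sostdc1, the mean of the dimmer group lay below 4.35, the log2 of the lowest array median. Signal above background was not shown there, so the sizes and the order of those differences are not established. In limma's test with Benjamini-Hochberg adjustment 7183 of 22180 genes were called, 3365 higher and 3818 lower, and 1853 of them differed at least 2-fold (1043 higher and 810 lower). The majority direction depended on the scaling: the share called higher was 46.8%, and 53.8% of 6904 calls when each array was centred on its median. The 3 v-Hras values and the 3 control values did not overlap for 42.4% of genes, where chance gives 10%.

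Proliferation genes rose throughout their lists. All 37 measured mitosis genes rose (median log2 difference 2.37, camera adjusted p = 2.26e-37), among them the kinesin gene Cenpe (4.28) and the proliferation marker Mki67 (3.77; 9.69 ± 0.05 against 5.91 ± 0.14, n = 3). Of 35 DNA replication genes 33 rose (34 when adjusted over the list alone) and none fell, with Mcm3 at 2.88 and Mcm5 at 2.59, both parts of the replicative helicase (camera adjusted p = 5.77e-26). Cyclin D1, Ccnd1, rose by 2.88 (limma adjusted p = 2.49e-10).

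Growth factor signalling genes rose with them. Of 7 EGF receptor ligand genes 6 rose and none fell, led by Hbegf (4.64) and Nrg1 (4.37, camera adjusted p = 2.2e-08). Of 22 MAPK output genes 17 rose and 3 fell (camera adjusted p = 6.34e-11), with the phosphatase gene Dusp5 at 3.94 and the urokinase receptor gene Plaur at 3.90, and with Plat (-1.81) and the feedback inhibitor gene Spry1 (-0.70) lower. In the matrix metalloproteinase and plasminogen list 11 of 19 rose and 4 fell (camera adjusted p = 0.000906), with Mmp1a at 4.10 and the inhibitor gene Timp3 at -2.42.

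The unfolded protein response lists moved unevenly. Of 18 ER chaperone genes 15 rose and none fell (median 0.72, camera adjusted p = 8.87e-09), with the oxidase gene Ero1a at 1.90, Hyou1 at 1.49 and Hspa5, which encodes the chaperone BiP, at 0.79 (limma adjusted p = 8.09e-06). Of 29 XBP1s-dependent genes 17 rose and 12 were not called (median 0.40, camera adjusted p = 1.01e-07), with Tram1 at 1.03, while Dnajb9 differed by -0.06 (limma adjusted p = 0.725). Of 28 PERK-ATF4 and amino acid response genes 25 rose and none fell (median 1.24, camera adjusted p = 2.55e-18), led by the amino acid transporter genes Slc7a3 (4.24) and Slc7a11 (3.08). The control mean of Slc7a3 lay below the lowest array median, so the size of its rise is not established. Ddit3, which encodes the stress factor CHOP, differed by 0.22 (limma adjusted p = 0.221). ER translocation and glycosylation genes were called higher (15 rose and 6 fell of 35, 8 adjusted over the list alone, camera adjusted p = 0.0201), a call lost with adjusted p = 0.217 with an estimated correlation; Tusc3 (-0.49) and Dad1 (-0.48), parts of the oligosaccharyltransferase, were among those that fell. ER-associated degradation genes split evenly, with 5 of 18 higher, such as Herpud1 (1.06) and Sel1l (0.74), and 5 lower, such as the ubiquitin ligase gene Rnf5 (-0.91, camera adjusted p = 0.217). Of 30 ER to Golgi transport genes 11 rose and 4 fell (camera adjusted p = 0.0994).

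Ern1 rose by 1.25 with v-Hras (limma adjusted p = 5.22e-05), and the difference of Xbp1 was 0.27 (limma adjusted p = 0.0372). The Xbp1 call was lost without control replicate 1 or 3 (0.0723 and 0.122), v-Hras scrambled replicate 1, 2 or 3 (0.0777, 0.108 and 0.0704) or Xbp1 shRNA replicate 1 (0.0508), and also with a further quantile normalization, cyclic loess, all probe sets, only the 6 arrays compared and a replicate block. Of 10 reported IRE1 cleavage substrates 9 fell (all 10 adjusted over the list alone; median -0.96, camera adjusted p = 4.47e-07). Id1 fell by 2.55 (5.99 ± 0.08 against 8.54 ± 0.15, n = 3; SE 0.11, limma adjusted p = 5.33e-09) and Col6a1 was lower too (-1.30), while Bloc1s1, the substrate most often used as a readout, differed by -0.31 (limma adjusted p = 0.0572). In the list of Id genes and SMAD1/5 targets 8 of 10 fell (9 adjusted over the list alone), Id2 at -2.74, and the inhibitory Smad7 alone rose (0.87, camera adjusted p = 8.76e-05). Dermal fibroblast markers, which share Pdgfrb with the cleavage substrates, were lower on the same arrays (9 of 12 fell, among them Lum at -2.00, and Pdgfra and Fbln1 rose by 1.12 and 0.58, camera adjusted p = 0.0022), with adjusted p = 0.0846 with an estimated correlation.

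Senescence regulators did not rise. Cdkn2b fell by 1.28 (limma adjusted p = 1.21e-06) and Cdkn2a was lower as well (-0.35, limma adjusted p = 0.0101). The difference of Cdkn1a was -0.23 (limma adjusted p = 0.0226), a call lost without control replicate 2 (0.0642) or v-Hras scrambled replicate 1, 2 or 3 (0.0658, 0.0614 and 0.0532), on centring each array on its median and with only the 6 arrays compared. Of 19 senescence-associated genes 9 rose, such as the chromatin gene Hmga2 (3.87), and 6 fell, such as Igfbp2 (-3.83) and Igfbp5 (-1.58, camera adjusted p = 0.278). The 24 p53 target genes split into 9 that rose, with Sesn2 at 1.80 and Ckap2 at 1.12, and 9 that fell, with the death receptor gene Fas at -1.98 and Sesn1 at -1.69; camera read the list as Up against a median of -0.16 and a mean of -0.09 (adjusted p = 0.989).

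Epidermal differentiation genes moved in opposite directions within their list. Of 45 suprabasal and cornified envelope genes 25 rose (26 adjusted over the list alone) and 13 fell (camera adjusted p = 2.16e-05). Lce3c rose by 4.53, while the spinous layer keratin genes Krt1 (-3.90) and Krt10 (-4.12) fell (limma adjusted p = 1.7e-09 and 2.78e-10). Basal genes split too, with 8 of 20 higher, such as the integrin genes Itga3 (3.25) and Itga2 (2.59), and 10 lower (11 adjusted over the list alone), such as Krt15 (-2.65) and Postn (-2.52); their median was -0.21, their mean 0.14 and the test Up (camera adjusted p = 0.505). The basal keratin gene Krt14 differed by -0.22 (limma adjusted p = 0.0338). Its call was lost without control replicate 1 or 2 (0.0591 and 0.0961), v-Hras scrambled replicate 1, 2 or 3 (0.0814, 0.0854 and 0.077) or Ire1a shRNA replicate 1 (0.0502), on centring each array on its median, with all probe sets, with only the 6 arrays compared and with a replicate block. Of 13 stress and simple epithelial keratin genes 3 rose, Krt23 by 3.18, and 2 fell, Krt80 at -0.84 and Krt17 at -0.81 (camera adjusted p = 0.751; median -0.08, mean 0.28, test Up). Hair follicle markers were lower (7 of 12 fell, such as Lgr5 at -2.26 and Msx2 at -2.07, and Krt75 alone rose, by 1.84, camera adjusted p = 0.0096), with adjusted p = 0.068 with an estimated correlation.

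Metabolic and inflammatory lists followed. Of 23 cholesterol and fatty acid synthesis genes 22 rose and none fell, with Dhcr7 at 2.19 and Lss at 1.85 (camera adjusted p = 3.73e-17). Glycolysis and hypoxia genes were called higher, with 17 of 23 up, such as Hk2 (2.95) and Vegfa (2.07), and 4 down, such as Bnip3 (-1.14, camera adjusted p = 1.09e-05), but adjusted p = 0.0846 with an estimated correlation. Of 28 cytokine and chemokine genes 15 rose, Il1a by 5.30, and 4 fell (7 adjusted over the list alone), Il18 at -3.12 and Tslp at -0.61 (camera adjusted p = 0.00275, adjusted p = 0.174 with an estimated correlation). Of 17 NF-kB target genes 5 rose, such as Ptgs2 (4.53) and Tnfaip2 (3.77), and 5 fell, such as Lcn2 (-1.28) and Sod2 (-1.07, camera adjusted p = 0.536; median -0.01, mean 0.39). Of 20 epithelial to mesenchymal transition genes 12 rose and 5 fell (6 adjusted over the list alone, camera adjusted p = 0.0143, adjusted p = 0.19 with an estimated correlation); the epithelial genes Epcam (2.07) and Cldn4 (1.68) led the rises and the mesenchymal genes Vim (-0.86) and Sparc (-0.81) the falls. Of 19 TGF-beta and SMAD3 target genes 8 rose, such as Itga5 (1.09), and 10 fell, such as Tgfbi (-2.76) and Acta2 (-2.28, camera adjusted p = 0.245).

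The remaining lists gave no call that held without each array. NRF2 targets (8 of 20 rose, Gsta4 by 3.34, and 5 fell, 6 adjusted over the list alone, Gsta3 at -2.18, camera adjusted p = 0.0955), heat shock genes (2 of 12 rose, Hsp90aa1 by 1.56 and Hspd1 by 0.87, and 5 fell, Hspa1a at -1.86, adjusted p = 0.276) and type I interferon genes (7 of 29 fell, Usp18 at -1.37, and 1 rose, adjusted p = 0.205) were not called by camera. Immune cell markers were called lower (5 of 14 fell, such as Lyz2 at -2.90 and H2-Ab1 at -2.25, camera adjusted p = 0.0236, adjusted p = 0.217 with an estimated correlation), and that call was lost without v-Hras scrambled replicate 1 (0.0509). Endothelial markers (2 of 10 rose, Pecam1 by 0.93, and Tek fell by 3.15, adjusted p = 0.675, median 0.13, mean -0.15), muscle markers (Acta1 alone rose, by 0.73, adjusted p = 0.375) and melanocyte markers (2 of 10 rose and 1 fell, adjusted p = 0.989) were not called by camera. The v-Hras mean of Tek lay below the lowest array median, so the size of its fall is not established. The other endothelial rise, of Kdr (0.46), was lost in 2 fits without 1 array (highest limma adjusted p = 0.0554, without v-Hras scrambled replicate 3). The melanocyte calls, Kit and Tyr higher and Dct lower, were all lost without v-Hras scrambled replicate 2 (limma adjusted p = 0.0603, 0.114 and 0.0757). Of the 19 lists called with camera's preset correlation, 14 higher and 5 lower, 12 were also called with an estimated correlation: the lists above given without an adjusted p for that correlation. Their camera adjusted p was then much larger, from 0.00217 for mitosis genes to 0.0459 for EGF receptor ligands.

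**Figure D2:**
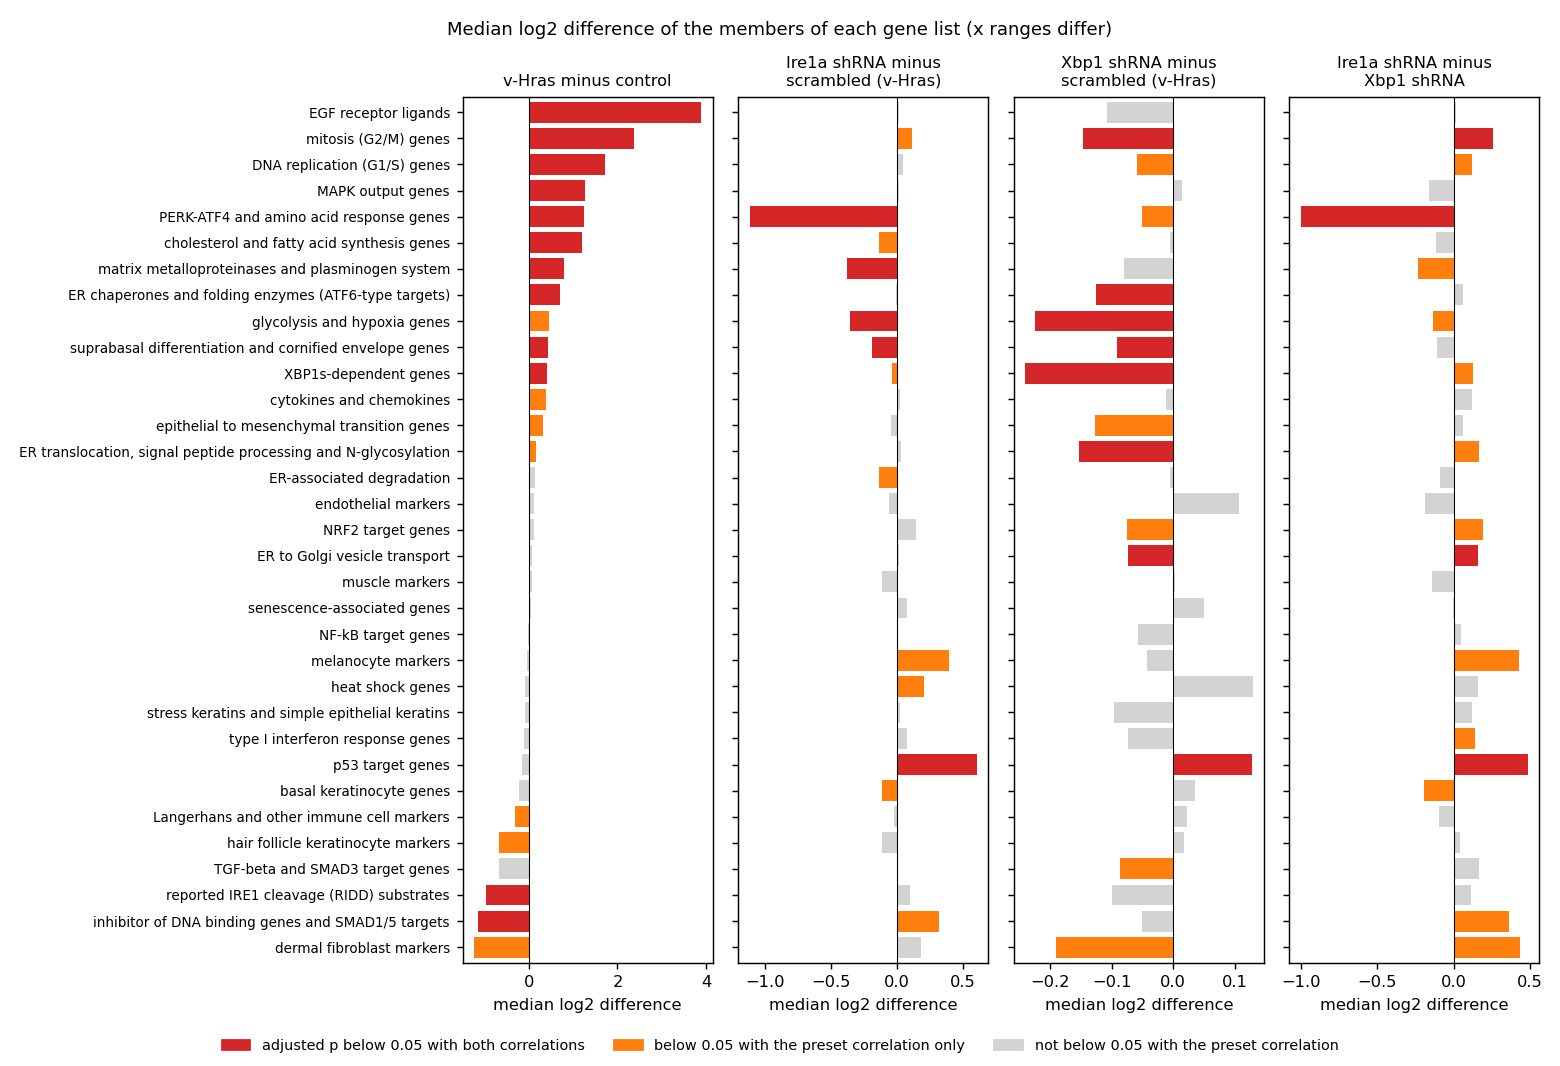
Median log2 difference of each fixed gene list (horizontal bars, with a separate axis range for each of 4 comparisons), coloured by whether camera called the list with both correlations, with the preset correlation only, or not. Mitosis genes reached 2.37 with v-Hras, amino acid response genes -1.12 with Ire1a shRNA, and XBP1s-dependent genes -0.24 with Xbp1 shRNA.

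The comparison of Ire1a shRNA with scrambled shRNA, both with v-Hras, asks what the Ire1a shRNA changed in cells that carry the oncogene. Amino acid response genes fell and p53 target genes and Id1 rose. The transporter gene Slc7a3 fell from 8.08 ± 0.22 to 5.05 ± 0.07 (SD, n = 3; log2 difference -3.03 ± 0.18, SE, limma adjusted p = 2.14e-06). The other large falls were in Mmp1b (-3.00), Slc7a11 (-2.52), Ctla2b (-2.44), Sprr2f (-2.42), the mitochondrial folate enzyme gene Aldh1l2 (-2.24), the glutathione-degrading enzyme gene Chac1 (-2.22), Pck2 (-2.16), the cystathionine gamma-lyase gene Cth (-2.15) and Spink7 (-2.12). Ern1 itself stood at -1.45, a smaller fall than in these genes. For the changes in this comparison, loss of IRE1 and an off-target effect of the Ire1a hairpin cannot be told apart. The largest fitted rise was in the steroid dehydrogenase gene Akr1c18 (3.26; 9.17 ± 0.17 against 5.91 ± 0.07, n = 3, limma adjusted p = 1.1e-07), followed by U90926 (3.15), Adamts5 (2.70), Gzmd (2.63), Rptn (2.46), the prostaglandin dehydrogenase gene Hpgd (2.37), Nkx2-9 (2.13), Trp53inp1 (1.90), Tek (1.86) and Rasl11a (1.86). The mean of the dimmer group lay below the lowest array median for Sprr2f, Adamts5, Gzmd, Tek and Rasl11a, whose sizes are not established. In limma's test with Benjamini-Hochberg adjustment 2902 of 22180 genes were called, 1607 higher and 1295 lower, and 271 differed at least 2-fold (102 higher and 169 lower). The majority direction depended on the scaling: the share called higher was 55.4%, and 47.3% of 2842 calls with cyclic loess. Groups did not overlap for 33.1% of genes, where chance gives 10%.

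Of 28 PERK-ATF4 and amino acid response genes 26 fell and none rose (median -1.12, camera adjusted p = 4.49e-37). Ddit3 fell by 1.29 (limma adjusted p = 4.9e-05), and Atf4 itself, chosen after its values were seen, fell by 1.12 (limma adjusted p = 2.33e-06). Of 24 p53 target genes 17 rose (21 adjusted over the list alone) and Sesn2 alone fell (median 0.61, camera adjusted p = 1.09e-16). Trp53inp1, Fas (1.68) and the death receptor gene Tnfrsf10b (1.48) were among the rises, and the cell cycle inhibitor gene Cdkn1a rose by 0.39 (12.02 ± 0.05 against 11.63 ± 0.01, n = 3, limma adjusted p = 0.00298). Sesn2 is also held by the amino acid response list; its fall (-0.42) was lost without v-Hras scrambled replicate 2 or 3 (0.066 and 0.0833) or Ire1a shRNA replicate 1, 2 or 3 (0.0579, 0.0534 and 0.0865).

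Id1 rose by 1.69, to 7.68 ± 0.04 from 5.99 ± 0.08 (n = 3, limma adjusted p = 3.39e-06), and Id3 by 1.13. In their list 3 of 10 rose (7 adjusted over the list alone) and Smad7 fell (camera adjusted p = 0.00238), a call lost with adjusted p = 0.0739 with an estimated correlation. The Smad7 call was lost without v-Hras scrambled replicate 1 or 2 (0.0817 and 0.0711) or Ire1a shRNA replicate 1, 2 or 3 (0.0607, 0.0707 and 0.0543). Melanocyte markers were higher on the same arrays, with 6 of 10 up (7 adjusted over the list alone), among them Oca2 by 0.94 and Mlana by 0.71 (camera adjusted p = 6.38e-05, adjusted p = 0.0992 with an estimated correlation). Id1 was the only cleavage substrate called of 10, and the list was not (median 0.10, camera adjusted p = 0.259); Bloc1s1 differed by -0.18 (limma adjusted p = 0.398).

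Glycolysis and hypoxia genes were lower, with 10 of 23 down (14 adjusted over the list alone), such as Ndrg1 (-2.10) and Vegfa (-1.94), and 1 up (2 adjusted over the list alone, camera adjusted p = 4.68e-09). Of 45 suprabasal genes 17 fell (21 adjusted over the list alone), such as Sprr2d (-1.92) and Lce3a (-1.61), and 5 rose (7 adjusted over the list alone), such as Rptn (2.46), Sprr3 (1.44) and Krt1 (1.31, limma adjusted p = 0.000123); camera called the list lower (adjusted p = 7.88e-05). In the metalloproteinase list 10 of 19 fell, such as Mmp1b (-3.00) and Mmp13 (-1.71), and 4 rose (5 adjusted over the list alone), with the inhibitor gene Timp3 at 1.80 (camera adjusted p = 0.000336). Krt10 differed by 0.16 and Krt14 by -0.05 (limma adjusted p = 0.504 and 0.775).

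No ER list was called with both correlations. ER-associated degradation genes were called lower, with 5 of 18 down (6 down and 1 up adjusted over the list alone), Herpud1 at -1.22 (camera adjusted p = 0.00832), but adjusted p = 0.149 with an estimated correlation. The 5 became 1 without v-Hras scrambled replicate 1. XBP1s-dependent genes were called lower with 5 of 29 down (7 adjusted over the list alone) and a median of -0.04 (camera adjusted p = 0.0191), but adjusted p = 0.201 with an estimated correlation, and the call was lost without v-Hras scrambled replicate 1 (0.0524). Limma called 1 of the 29 lower without that array or Ire1a shRNA replicate 1. Dnajb9, an XBP1s target, differed by -0.41 (limma adjusted p = 0.0339). That call was lost without v-Hras scrambled replicate 1, 2 or 3 (0.072, 0.0765 and 0.118) or Ire1a shRNA replicate 1 or 2 (0.121 and 0.13), on centring each array on its median, with all probe sets and with only the 6 arrays compared. Of 18 ER chaperone genes 4 fell, such as Ero1a (-0.89) and Creld2 (-0.55), and 1 rose (camera adjusted p = 0.0933); Hspa5 differed by -0.11 (limma adjusted p = 0.468). ER translocation genes (3 rose and 3 fell of 35, 3 and 4 adjusted over the list alone, adjusted p = 0.989) and ER to Golgi genes (3 of 30 rose, Sec23a by 0.63, adjusted p = 0.494) were not called by camera. Without 1 array the chaperone falls numbered 2 at the lowest and the ER to Golgi rises 2. The translocation falls numbered 0 without v-Hras scrambled replicate 1 or Ire1a shRNA replicate 1 or 3. The translocation rises numbered 0 without v-Hras scrambled replicate 3 or Ire1a shRNA replicate 2 or 3. The chaperone rise was lost without any 1 v-Hras scrambled or Ire1a shRNA array.

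Proliferation markers stayed near their v-Hras level. Mki67 differed by 0.06 (limma adjusted p = 0.745), and 1 of 37 mitosis genes was called (0 adjusted over the list alone). None was without v-Hras scrambled replicate 1 or 3 or Ire1a shRNA replicate 1 or 3. The list was called higher (median 0.11, camera adjusted p = 0.0287), with adjusted p = 0.309 with an estimated correlation, and not without v-Hras scrambled replicate 1 (0.053) or Ire1a shRNA replicate 1 (0.0932). Ccnd1 fell by 0.41 (limma adjusted p = 0.00651). Cdkn2a differed by 0.08 and Cdkn2b by 0.09 (limma adjusted p = 0.69 and 0.677). Of 22 MAPK output genes 5 fell (8 adjusted over the list alone), such as Etv5 at -0.97, and 2 rose (4 adjusted over the list alone, camera adjusted p = 0.264; median 0.01, mean -0.09). Among EGF receptor ligands Ereg rose by 0.70 while Tgfa (-0.77) and Hbegf (-0.65) fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.459).

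Further lists called lower with the preset correlation were cholesterol and fatty acid synthesis (7 of 23 fell, such as Msmo1 at -0.83, and 2 rose, such as Elovl6 by 0.88, 8 and 3 adjusted over the list alone, camera adjusted p = 0.00204, adjusted p = 0.17 with an estimated correlation) and basal genes (7 of 20 fell, such as Itga2 at -1.08 and Lamb3 at -0.83, and 2 rose, 9 and 3 adjusted over the list alone, camera adjusted p = 0.0096, adjusted p = 0.217 with an estimated correlation). Heat shock genes were called higher (4 of 12 rose, 5 adjusted over the list alone, Hspa1a by 0.68, and 1 fell, camera adjusted p = 0.00385, adjusted p = 0.122 with an estimated correlation). Of 13 lists called, 5 higher and 8 lower, 5 held with an estimated correlation: amino acid response, p53, glycolysis and hypoxia, suprabasal and metalloproteinase genes. Their camera adjusted p was then 0.00731, 0.00165, 0.0328, 0.0227 and 0.0327 in that order. Cytokines and chemokines (3 of 28 rose, such as Il18 by 1.54 and Ccl2 by 1.28, and 9 fell, such as Il1f9 at -0.75, or 9 and 11 adjusted over the list alone, camera adjusted p = 0.725) and senescence-associated genes (7 of 19 rose, Igfbp2 by 1.35, and 4 fell, 8 and 5 adjusted over the list alone, camera adjusted p = 0.646) went both ways.

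The comparison of Xbp1 shRNA with scrambled shRNA, both with v-Hras, asks what the Xbp1 shRNA changed. Camera called 4 of 5 ER lists lower relative to other genes, while limma called few of their members. Most XBP1s-dependent genes are also members of the other ER lists, so these calls are not independent results. Uqcrc2, a subunit of mitochondrial complex III, fell by 1.69 (8.34 ± 0.09 against 10.03 ± 0.04, SD, n = 3; SE 0.08, limma adjusted p = 2.44e-06). Igfbp2 (-1.58), Scel (-1.35), Il18 (-1.27), Map3k3 (-1.19), the hexosamine pathway gene Uap1 (-1.15), Prnd (-1.13), Prpsap2 (-1.12) and the adaptor complex gene Ap3m1 (-1.08) also fell. Xbp1 itself stood at -1.09, a smaller fall than in most of these genes. Loss of XBP1 and an off-target effect of the Xbp1 hairpin cannot be told apart here. The skeletal actin gene Acta1 rose by 1.51 (8.36 ± 0.19 against 6.85 ± 0.08, n = 3, limma adjusted p = 0.000308), Sncg by 1.37, Ppp2r2c by 1.15, Mmp1b by 1.13, Rrad by 1.00 and Fam78b by 0.94. The scrambled mean of Ppp2r2c lay below the lowest array median, so the size of its rise is not established. With only the 6 arrays compared the calls of Scel, Lman1, Derl1, Fas and Btg2 were lost, and with the mean of a gene's probe sets that of Prnd. In limma's test with Benjamini-Hochberg adjustment 463 of 22180 genes were called, 152 higher and 311 lower, and 24 differed at least 2-fold. The share called higher was 32.8%, and 17.4% of 528 calls when each array was centred on its median. Groups did not overlap for 23.2% of genes, where chance gives 10%. The count of 463 became 166, 153 and 165 without v-Hras scrambled replicate 1, 2 or 3, and 219, 203 and 222 without Xbp1 shRNA replicate 1, 2 or 3.

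Of 29 XBP1s-dependent genes 4 fell (14 adjusted over the list alone) and none rose (median -0.24, camera adjusted p = 2.45e-12), with the cargo receptor gene Lman1 at -0.45 (8.59 ± 0.03 against 9.04 ± 0.01, n = 3, limma adjusted p = 0.00817). Camera also called lower the ER translocation and glycosylation genes (3 of 35 fell, 9 adjusted over the list alone; median -0.15, camera adjusted p = 4.78e-09), with Magt1 at -0.68. The same held for ER chaperones (4 of 18 fell, 5 adjusted over the list alone; median -0.13, camera adjusted p = 6.23e-06) and ER to Golgi genes (1 of 30 fell, 3 adjusted over the list alone; median -0.07, adjusted p = 0.000215). These counts depended on single arrays. Without any 1 v-Hras scrambled array limma called 1 XBP1s-dependent, 1 translocation and 0 chaperone genes lower. Without Xbp1 shRNA replicate 1, 2 or 3 it called 1, 1 and 2 XBP1s-dependent, 1, 1 and 2 translocation and 0, 1 and 0 chaperone genes. Without Ire1a shRNA replicate 1, 2 or 3 these were 1, 1 and 2, 1, 1 and 1, and 1, 1 and 2. Translocation genes numbered 1 without control replicate 1 and 2 without control replicate 3. Hspa5 differed by 0.03 and Dnajb9 by -0.12 (limma adjusted p = 0.899 and 0.685). The ER-associated degradation list was not called (camera adjusted p = 0.0749), though Derl1 fell by 0.51, and without Xbp1 shRNA replicate 3 it was (0.0396).

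Of 24 p53 target genes 5 rose (9 adjusted over the list alone), such as Fas (0.82) and Btg2 (0.73), and Zmat3 fell by 0.60 (median 0.13, camera adjusted p = 0.000803). Camera called lower the glycolysis and hypoxia genes (4 of 23 fell and none rose, 11 and 1 adjusted over the list alone, such as Adm at -0.79 and Pfkl at -0.54, camera adjusted p = 7.8e-08). It called the mitosis genes lower too (median -0.15, camera adjusted p = 2.5e-07), with 2 of 37 called by limma (5 adjusted over the list alone), and Mki67 differed by -0.07 (limma adjusted p = 0.791). Both mitosis calls were lost without any 1 v-Hras scrambled or Xbp1 shRNA array. Without v-Hras scrambled replicate 1, 2 or 3 the adjusted p was 0.0855, 0.0855 and 0.1 for Kif2c and 0.0504, 0.131 and 0.126 for Ccnb2. Without Xbp1 shRNA replicate 1, 2 or 3 it was 0.0879, 0.0506 and 0.0853 for Kif2c and 0.093, 0.116 and 0.0664 for Ccnb2. Ccnb2 was lost without Ire1a shRNA replicate 3 as well (0.055). Both were also lost with only the 6 arrays compared and with a replicate block. In the suprabasal list 3 of 45 fell (11 adjusted over the list alone) and Tgm3, an epidermal transglutaminase gene, rose by 0.93 (camera adjusted p = 4.02e-06). Without v-Hras scrambled replicate 1, 2 or 3 the p53 rises numbered 2, 3 and 3. Without any 1 of those arrays 2 glycolysis genes and no suprabasal gene fell. Without Xbp1 shRNA replicate 1, 2 or 3 there were 3, 2 and 3 p53 rises, 3, 3 and 2 glycolysis falls and 2, 0 and 2 suprabasal falls. These 8 lists, 1 higher and 7 lower, held with an estimated correlation, of 14 called. Their camera adjusted p was then between 0.00841 (XBP1s-dependent genes) and 0.0497 (mitosis genes). Id1 differed by -0.42 (limma adjusted p = 0.0769), Cdkn1a by 0.15 (0.358), Cdkn2a by 0.03 (0.913), Cdkn2b by 0.24 (0.292), Ddit3 by -0.35 (0.194), Bloc1s1 by -0.09 (0.784), Krt1 by 0.33 (0.303), Krt10 by 0.16 (0.608) and Krt14 by -0.07 (0.733). Ccnd1 differed by 0.39 (limma adjusted p = 0.0377). Its call was lost without v-Hras scrambled replicate 1, 2 or 3 (0.114, 0.11 and 0.127), Ire1a shRNA replicate 1, 2 or 3 (0.0663, 0.0606 and 0.0572) or Xbp1 shRNA replicate 1, 2 or 3 (0.112, 0.0802 and 0.112), and also with a further quantile normalization, on centring each array on its median, with all probe sets, with only the 6 arrays compared and with a replicate block.

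The other 6 lists were called lower by camera and were lost with an estimated correlation. TGF-beta and SMAD3 targets (5 of 19 fell and none rose, 7 and 3 adjusted over the list alone, such as Thbs1 at -0.96 and Acta2 at -0.77) had a camera adjusted p = 0.00275, and adjusted p = 0.149 with an estimated correlation. Epithelial to mesenchymal transition genes (2 of 20 fell, 5 adjusted over the list alone, Fn1 at -0.61, camera adjusted p = 0.00235) had adjusted p = 0.122 with an estimated correlation, and dermal fibroblast markers on the same arrays (2 of 12 fell, camera adjusted p = 0.00457) had adjusted p = 0.105 with an estimated correlation. DNA replication genes (2 of 35 fell, 5 adjusted over the list alone, camera adjusted p = 0.00179) had adjusted p = 0.216 with an estimated correlation. Amino acid response genes (1 of 28 fell, 3 adjusted over the list alone; median -0.05, camera adjusted p = 0.00215) had adjusted p = 0.275 with an estimated correlation, and their call was lost without v-Hras scrambled replicate 1 (0.0835). NRF2 targets (none of 20 called by limma, 3 lower adjusted over the list alone, camera adjusted p = 0.0236) had adjusted p = 0.126 with an estimated correlation, and their call was lost without v-Hras scrambled replicate 1 (0.119) or Xbp1 shRNA replicate 3 (0.0709). The counts by limma depended on single arrays here too. Without any 1 v-Hras scrambled array it called no dermal fibroblast, DNA replication or amino acid response gene lower. Without any 1 Xbp1 shRNA array it called no fibroblast or amino acid response gene lower, and without Ire1a shRNA replicate 1 or 3 no amino acid response gene. Without Xbp1 shRNA replicate 1, 2 or 3 it called 0, 2 and 1 replication genes. Without any 1 array of either group it called 1 transition gene lower. TGF-beta targets numbered 4, 4 and 3 without v-Hras scrambled replicate 1, 2 or 3 and 5, 3 and 3 without Xbp1 shRNA replicate 1, 2 or 3. Cleavage substrates were not called (median -0.10, camera adjusted p = 0.198).

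**Figure D3:**
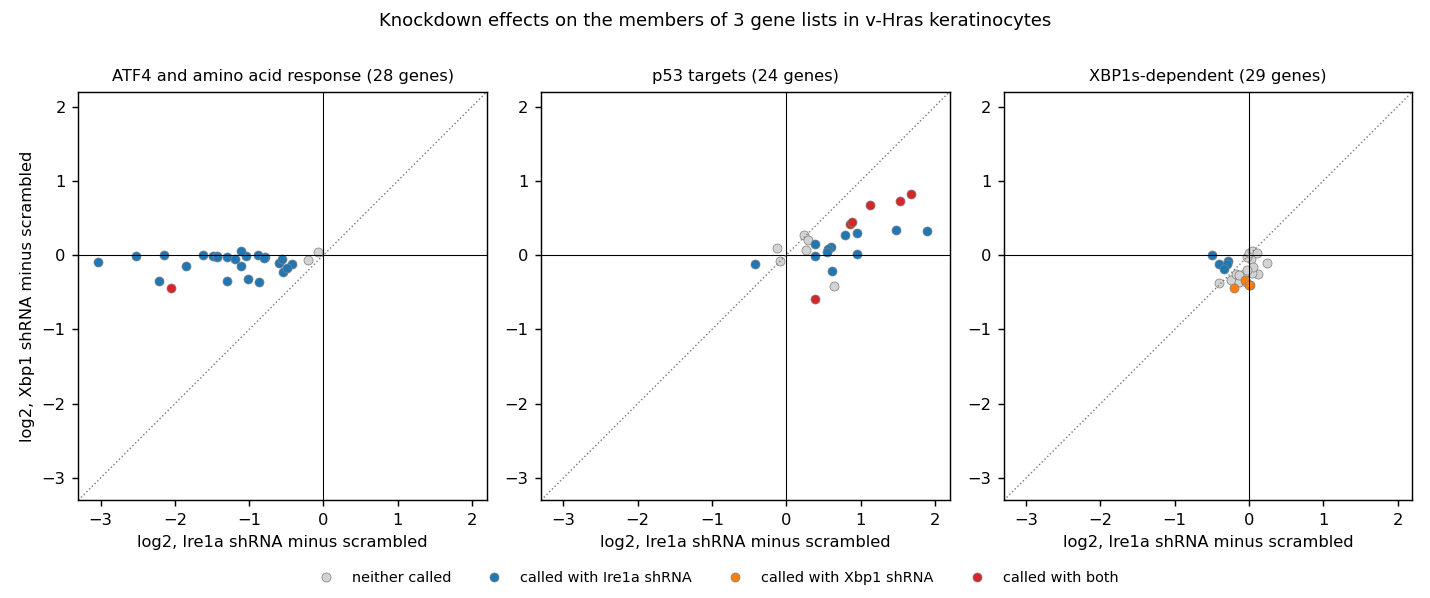
Log2 difference with Xbp1 shRNA against log2 difference with Ire1a shRNA, both relative to v-Hras with scrambled shRNA, for the members of 3 lists, with points coloured by the knockdown in which limma called the gene and a dotted line of equality. Amino acid response genes lie near 0 for Xbp1 shRNA and reach -3.03 for Ire1a shRNA, and p53 targets lie mostly above 0 on both axes.

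The direct comparison of Ire1a with Xbp1 shRNA asks where the effects of the knockdowns differ. Amino acid response genes were lower and p53 targets higher with Ire1a shRNA. Mmp1b had the widest fitted margin among genes lower with Ire1a shRNA (5.48 ± 0.29 against 9.61 ± 0.02, SD, n = 3; log2 difference -4.13 ± 0.13, SE, limma adjusted p = 3.39e-08), followed by Slc7a3 (-2.93), Slc7a11 (-2.50), Acta1 (-2.37), Prl7b1 (-2.24), Cth (-2.15), Sprr2f (-2.09), Vegfa (-2.08), Aldh1l2 (-2.05) and Ndrg1 (-2.01). The cytotoxic protease gene Gzmd was higher by 3.56 (limma adjusted p = 3.68e-05), U90926 by 3.47, Rptn by 3.24, Igfbp2 by 2.94, Hpgd by 2.84, Il18 by 2.81, Adamts5 by 2.64, Serpinb9b by 2.46, Timp3 by 2.36 and Akr1c18 by 2.35. The mean of the dimmer group lay below the lowest array median for Prl7b1, Sprr2f, Gzmd, Rptn and Adamts5, whose sizes are not established. Id1 was higher by 2.11 (7.68 ± 0.04 against 5.57 ± 0.19, n = 3, limma adjusted p = 6.16e-07), Krt1 by 0.97 and Id3 by 1.66, and Ddit3 was lower (-0.94, limma adjusted p = 0.000342), as was Ccnd1 (-0.79). Cdkn1a differed by 0.24 (limma adjusted p = 0.0323), a call lost without v-Hras scrambled replicate 2 (0.0505), Ire1a shRNA replicate 1, 2 or 3 (0.0706, 0.0664 and 0.117) or Xbp1 shRNA replicate 1, 2 or 3 (0.0783, 0.0905 and 0.0702), and also with all probe sets, only the 6 arrays compared and a replicate block. Dnajb9, Hspa5, Bloc1s1, Cdkn2a, Cdkn2b, Mki67, Krt10 and Krt14 differed by -0.29, -0.14, -0.09, 0.05, -0.15, 0.13, 0.00 and 0.02 with limma adjusted p between 0.115 and 0.995. In limma's test with Benjamini-Hochberg adjustment 3674 of 22180 genes were called, 2077 higher and 1597 lower with Ire1a shRNA, and 301 differed at least 2-fold (140 higher and 161 lower). The share called higher was 56.5%, 46.5% at 2-fold, and 71.0% of 3875 calls when each array was centred on its median. Groups did not overlap for 35.5% of genes, where chance gives 10%.

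Of 28 amino acid response genes 23 were lower with Ire1a shRNA than with Xbp1 shRNA (26 adjusted over the list alone) and none higher (median -1.001, camera adjusted p = 2.86e-27). Of 24 p53 targets 18 were higher, such as Trp53inp1 (1.58) and Tnfrsf10b (1.14), and none lower (1 adjusted over the list alone, camera adjusted p = 8.57e-12). Mitosis genes were higher (14 of 37, 20 adjusted over the list alone, such as Cdc20 by 0.83 and Aurka by 0.61, camera adjusted p = 6.25e-08), and so were ER to Golgi genes (9 of 30, 10 adjusted over the list alone, with Sec23a at 0.64, adjusted p = 0.000662). These 4 lists held with an estimated correlation, of 15 called. Their camera adjusted p was then between 0.00217 (p53 targets) and 0.0437 (mitosis genes). The 14 mitosis genes became 6 without Ire1a shRNA replicate 3 or Xbp1 shRNA replicate 1. The 9 ER to Golgi genes became 3 without Ire1a shRNA replicate 3 or Xbp1 shRNA replicate 2. XBP1s-dependent genes were higher with Ire1a than with Xbp1 shRNA (7 of 29 higher and Arfgap3 lower, 12 and 2 adjusted over the list alone, camera adjusted p = 0.0096), with adjusted p = 0.17 with an estimated correlation. The 7 became 3 without Ire1a shRNA replicate 1 or 3 or Xbp1 shRNA replicate 1 or 2. The Arfgap3 call was lost without Ire1a shRNA replicate 2 (0.0511). ER translocation genes (8 of 35 higher, 13 adjusted over the list alone, with Magt1 at 0.64, camera adjusted p = 0.000141) had adjusted p = 0.0766 with an estimated correlation.

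Melanocyte markers were higher with Ire1a shRNA (7 of 10, Mlana by 0.95, camera adjusted p = 6.18e-05, adjusted p = 0.0992 with an estimated correlation), as were dermal fibroblast markers (4 of 12, 6 adjusted over the list alone, Dcn by 0.97 and Col1a1 by 0.95, camera adjusted p = 0.000906, adjusted p = 0.068 with an estimated correlation) and Id genes and SMAD1/5 targets (6 of 10 higher and Smad7 lower, camera adjusted p = 0.00422, adjusted p = 0.0846 with an estimated correlation). The Smad7 call was lost without Ire1a shRNA replicate 1 or 2 (0.0517 and 0.0615) or Xbp1 shRNA replicate 1 or 3 (0.0513 and 0.0669). DNA replication genes (10 of 35, 12 adjusted over the list alone, with Rrm2 at 0.83, camera adjusted p = 0.00188, adjusted p = 0.216 with an estimated correlation) and NRF2 targets (9 of 20 higher, Gsta4 by 1.32, and 2 lower, among them Gsr at -0.56, 10 and 3 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.126 with an estimated correlation) were higher too. The 10 DNA replication genes became 5 without Ire1a shRNA replicate 1 or 3 or Xbp1 shRNA replicate 2, and the 9 NRF2 targets 5 without Ire1a shRNA replicate 1. Basal genes (6 of 20 lower, Itga2 at -1.12, and 3 higher, 9 and 3 adjusted over the list alone, camera adjusted p = 0.0128, adjusted p = 0.23 with an estimated correlation) and glycolysis and hypoxia genes (9 of 23 lower and 4 higher, 10 and 5 adjusted over the list alone, Adm by 1.13, camera adjusted p = 0.0242, adjusted p = 0.301 with an estimated correlation) were lower. Metalloproteinase genes were called lower (9 of 19 lower and 6 higher, camera adjusted p = 0.0409, adjusted p = 0.159 with an estimated correlation). That call was lost without control replicate 1 (0.0513), v-Hras scrambled replicate 1 (0.0504), Ire1a shRNA replicate 1 (0.0593) or Xbp1 shRNA replicate 1 (0.085). Interferon genes were called higher (3 of 29 higher, 6 adjusted over the list alone, Ifit2 by 0.92, and 1 lower, camera adjusted p = 0.0467, adjusted p = 0.127 with an estimated correlation). That call was lost without control replicate 2 (0.0555), Ire1a shRNA replicate 2 or 3 (0.0535 and 0.0816) or Xbp1 shRNA replicate 2 (0.0954). The 1 lower gene, Zbp1 (-0.37), lost its call in 6 fits without 1 array (highest limma adjusted p = 0.13). It was also lost under 6 other settings, among them a further quantile normalization and a variance trend with robust estimation.

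Each knockdown group was also set against the control without v-Hras, to show how far it lay from cells without the oncogene. With v-Hras and Ire1a shRNA limma called 7301 genes (3687 higher and 3614 lower), and with v-Hras and Xbp1 shRNA 7207 (3503 higher and 3704 lower), next to 7183 with v-Hras and scrambled shRNA. The share called higher with Ire1a shRNA was 50.5%, 49.1% with a further quantile normalization, 49.5% with all probe sets and 60.4% when each array was centred on its median, so neither direction held the majority throughout. With Xbp1 shRNA it was 48.6%, 50.1% without the dimmest 40% of genes and 53.9% of the 1834 genes that differed at least 2-fold. Id1 was below control by a log2 difference of -0.86 with Ire1a shRNA (limma adjusted p = 5.74e-05) and -2.97 with Xbp1 shRNA (1.47e-09). Ccnd1 was above control by 2.47 and 3.27 and Mki67 by 3.84 and 3.71 with Ire1a and Xbp1 shRNA. Krt1 stood at -2.59 and -3.57 and Krt10 at -3.96 with either. Hspa5 was above control by 0.68 and 0.82, Cdkn2b stood at -1.19 and -1.04, and Krt14 at -0.27 and -0.29. Both Krt14 calls (limma adjusted p = 0.0124 and 0.008) were lost with only the 6 arrays compared (0.0651 and 0.0667), and the first also on centring each array on its median (0.0647). Ddit3 was below control with Ire1a shRNA (-1.08, limma adjusted p = 2.76e-05) and differed by -0.14 with Xbp1 shRNA (0.458), and Dnajb9 stood at -0.47 (0.00629) and -0.19 (0.254). Bloc1s1 was at -0.49 with Ire1a shRNA (limma adjusted p = 0.00537). Its difference between the knockdown groups was -0.09 (limma adjusted p = 0.68), so that value is not shown to be particular to Ire1a shRNA. Cdkn1a stood at 0.16 (0.103) and -0.08 (0.417). The first Cdkn1a value was called with a further quantile normalization (0.0204), on centring each array on its median (0.0252) and with the offset (0.025). It was also called without the dimmest 40% of genes (0.042) and with a variance trend and robust estimation (0.0024).

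Overlaps of the calls were counted for the knockdowns with each other and with v-Hras. Genes called the same way with Ire1a and with Xbp1 shRNA numbered 128, 53 higher and 75 lower, and 72 were called in opposite directions. Independent lists of those sizes would share 11 and 18.2, a figure that leaves out the shared scrambled arrays. Groups simulated without any effect around shared arrays had a mean of 0.1 calls per comparison, so their mean of 0 shared genes in 20 simulations follows from the near absence of calls and gives no expectation for lists of these sizes. The covariance of the log2 differences was 0.0143 beside a simulated 0.0116, and their correlation across genes, which are not independent replicates, 0.224 beside a simulated 0.502. The 128 became 31, 29 and 32 without v-Hras scrambled replicate 1, 2 or 3, 68, 81 and 75 without Ire1a shRNA replicate 1, 2 or 3, and 40, 44 and 52 without Xbp1 shRNA replicate 1, 2 or 3. Of the genes called with Ire1a shRNA, 1515 (52.2%) were called in the direction opposite to v-Hras, 829 raised by v-Hras and lower with the knockdown and 686 the reverse, and 472 in the same direction. Independent lists would give 196 and 277, and the simulation, again with almost no calls, 0. The covariance, with the sign turned, was 0.0746 beside a simulated 0.0116. Of the genes called with Xbp1 shRNA, 201 (43.4%) were opposite to v-Hras, 137 and 64 by direction, and 139 in the same direction. Independent lists would give 47.2 and 26.2 and the same simulation 0.05, and the covariance was 0.0200 beside 0.0116. The 201 became 59, 61 and 63 without v-Hras scrambled replicate 1, 2 or 3 and 82, 75 and 94 without Xbp1 shRNA replicate 1, 2 or 3. The 3 v-Hras scrambled arrays enter every one of these comparisons and are too few to split, so part of each excess over independent lists may come from the shared arrays. No independent expectation was computed for the 72, 472 and 139 calls in the other relation. The excesses are therefore not shown to be particular to the relation counted.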

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

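The tests of the amino acid response pattern, of the fibroblast markers as a source for Col6a1, Pdgfrb and Sparc, and of cleavage by IRE1 were chosen after the results were seen.

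Among named genes, 18 were called in opposite directions with Ire1a and with Xbp1 shRNA, of 72 genes in all. Values are log2 Ire1a minus Xbp1 shRNA, with the knockdown effects in brackets in that order. The first value is the difference of the bracketed effects, so limma's direct test (largest adjusted p = 0.000111, for Timp1) follows from the selection of opposite calls and adds no support. Matrix and protease genes were split: Mmp1b -4.126 (-3.00, 1.13), Timp3 2.358 (1.80, -0.56), Timp1 1.252 (0.56, -0.69) and Thbs1 1.479 (0.52, -0.96). Secreted factors and growth regulators were Igfbp2 2.935 (1.35, -1.58), Il18 2.811 (1.54, -1.27), Tslp -1.221 (-0.32, 0.90), Adm 1.131 (0.34, -0.79) and Ccnd1 -0.794 (-0.41, 0.39). The others were Acta1 -2.367 (-0.86, 1.51), Id3 1.662 (1.13, -0.54), Map3k3 1.453 (0.27, -1.19), Nrk -1.996 (-0.95, 1.04), Prnd 2.269 (1.14, -1.13), Rptn 3.238 (2.46, -0.78), Rrad -1.53 (-0.53, 1.00), Rrm2 0.835 (0.35, -0.49) and Zmat3 0.984 (0.39, -0.60). A call against the scrambled arrays was lost in some fits without 1 array with Ire1a shRNA for Adm (highest limma adjusted p = 0.1), Rrm2 (0.0649) and Timp1 (0.0851) and, with Xbp1 shRNA, for Ccnd1 (0.127), Id3 (0.0718), Nrk (0.105), Rptn (0.153), Rrm2 (0.0608) and Timp1 (0.11). With Ire1a shRNA the highest value came without v-Hras scrambled replicate 3 for Adm, Ire1a shRNA replicate 2 for Rrm2 and Ire1a shRNA replicate 3 for Timp1. With Xbp1 shRNA it came without v-Hras scrambled replicate 1 for Timp1, replicate 2 for Id3 and Rptn, and replicate 3 for Ccnd1, Nrk and Rrm2. Under other settings only calls with Xbp1 shRNA were lost: with only the 6 arrays compared those of Timp3, Timp1, Id3, Rrm2, Rptn and Ccnd1, with a replicate block those of Nrk, Rptn and Ccnd1, with all probe sets those of Rptn and Ccnd1, with the mean of a gene's probe sets those of Prnd and Rrm2, and with a further quantile normalization and on median centring that of Ccnd1.

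Of 10272 probe sets without exactly 1 gene symbol, which no comparison above uses, limma called 1392 with v-Hras, 290 with Ire1a shRNA and 43 with Xbp1 shRNA. With 3 arrays per group, single arrays were not tested as outliers.

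Amino acid response genes were lower with Ire1a shRNA, by 89.3% of the v-Hras rise of their mean (95% interval 81.3 to 97.4). That rise includes Slc7a3, whose control mean lay below the lowest array median. A shift of the scrambled arrays alone is argued against by the list's median of -1.001 between the Ire1a and Xbp1 shRNA arrays, a comparison those arrays do not enter. Fewer v-Hras transduced cells is argued against by the mitosis list, for which the share of the v-Hras rise lost was -5.03% (-8.59 to -1.46), a slight further rise. Loss of XBP1 activity as far as the Xbp1 shRNA reached it is argued against by the list's median of -0.051 there. XBP1s-dependent genes had a median of -0.24 with Xbp1 shRNA and -0.04 with Ire1a shRNA. The Xbp1 knockdown was partial (-1.09) and XBP1s was not measured, so a deeper loss was not tested. Camera did call the amino acid response list lower with Xbp1 shRNA (adjusted p = 0.00215), but not with an estimated correlation (0.275). A role of IRE1 apart from XBP1 and an off-target effect of the Ire1a hairpin both stay open, with no test here that parts them.

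Melanocyte markers were higher with Ire1a shRNA. Dct, Tyrp1, Pmel and Mlana had a mean of 0.484 (95% interval 0.339 to 0.629). The planned comparison of that mean with the markers called decides nothing, since all 4 genes are among the 6 called. The 4 markers not called lay between -0.04 and 0.23. More melanocytes in these cultures and a change of expression within them cannot be told apart, since arrays of mixed cells hold no measure of cell number.

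Reported IRE1 cleavage substrates were lower with v-Hras. The 7 members other than Col6a1, Pdgfrb and Sparc had a median of -1.018. That argues against fewer fibroblasts as the whole cause only if these 7 are expressed mainly outside fibroblasts, which was not tested here. For Col6a1, Pdgfrb and Sparc (95% interval of their mean -1.12 to -0.88) the 11 fibroblast markers other than Pdgfrb were lower as a set. Their mean was -0.841 (-0.95 to -0.73), the outcome predicted under fibroblast loss, though 8 fell, 2 rose and 1 was not called. Fibroblast loss and regulation cannot be told apart for these genes, since the arrays hold no measure of cell number. Under Ire1a shRNA the list had a mean of 0.217 (0.145 to 0.29), beside -1.072 with v-Hras. Without Id1 the mean under Ire1a shRNA was 0.05 (-0.01 to 0.12), so the other members showed no clear recovery as a set. IRE1 activity and mRNA stability were not analysed here, so cleavage and lower transcription cannot be told apart for the list.

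The 6 arrays of each comparison can be split into 3 and 3 in 10 ways, and 1 of the 10, the labelled split, gave the highest count each time. With 10 splits no share under 0.05 can be reached. Limma called 7183, 2902, 463, 3674, 7301 and 7207 genes in the labelled splits of the v-Hras, Ire1a shRNA, Xbp1 shRNA and direct comparisons and of the Ire1a and Xbp1 shRNA groups against control, and at most 0 in every other split, where genes with unadjusted p under 0.05 numbered at most 1136. Camera called 19, 13, 14 and 15 lists in the first 4 comparisons and at most 14, 5, 9 and 8 in the other splits. Every other split mixes arrays of both groups on each side. A real group difference then widens the spread within the sides and in part remains between them. Neither the gene counts nor the list counts of those splits are therefore a chance level.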

How the results depend on the processing

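The offset of 16 was chosen after seeing the data. Ern1 with Ire1a shRNA and Xbp1 with Xbp1 shRNA stayed called and lower under every alternative; without 1 array they ranged from -1.57 to -1.38 and from -1.12 to -1.06. No call of a named gene in the first 4 comparisons changed its sign under an alternative. Of the calls against control given for Id1, Ccnd1, Mki67, Krt1, Krt10, Hspa5, Cdkn2b, Krt14, Ddit3, Dnajb9 and Bloc1s1, only those of Krt14 were lost: with Ire1a shRNA on median centring (0.0647) and with only the 6 arrays compared (0.0651), with Xbp1 shRNA with only the 6 arrays compared (0.0667). None changed its sign. Among differences that were not called, signs changed on median centring for Hspa5 and Cdkn2a with Xbp1 shRNA and Krt10 in the direct comparison, and without 1 array for Dnajb9 with v-Hras, for Cdkn2a in the Ire1a shRNA, Xbp1 shRNA and direct comparisons, and for Krt10 and Krt14 in the direct comparison. The Krt10 sign also changed with a further quantile normalization. The majority direction of calls turned with v-Hras on median centring (46.8% to 53.8% higher) and at 2-fold (56.3%), with Ire1a shRNA under cyclic loess (55.4% to 47.3%) and at 2-fold (37.6%), and in the direct comparison at 2-fold (56.5% to 46.5%). Against control it turned with Ire1a shRNA on a further quantile normalization (50.5% to 49.1%) and with all probe sets (49.5%), and with Xbp1 shRNA without the dimmest 40% of genes (48.6% to 50.1%) and at 2-fold (53.9%). Of 80 values named as largest rises or falls, 29 had a dimmer group below the lowest array median, so signal over background leaves their sizes not established.

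Counts for v-Hras, Ire1a shRNA, the direct comparison and the groups against control stayed within 1.5 times under the alternatives other than the fold threshold. The Xbp1 shRNA count of 463, the 128 shared calls and the 201 calls opposite to v-Hras did not: they became 955, 287 and 439 without the dimmest 40% of genes, 1095, 333 and 503 with a variance trend and robust estimation, 759, 217 and 318 with array weights, 1041, 317 and 485 with the offset, 117, 27 and 51 with only the 6 arrays compared, and 271, 58 and 112 with a replicate block. With all probe sets the shared calls became 79. Fewer genes share the adjustment without dim genes, more do with all probe sets, and 6 arrays leave fewer degrees of freedom; otherwise the cause was not tested. Replicate numbers do not pair the arrays: residuals correlated at -0.01 in the mean for 18 pairs with the same number and 0.005 for 36 with different numbers. Requiring at least a 2-fold difference, which drops smaller changes by construction, left 1853 genes with v-Hras, 271 with Ire1a shRNA, 24 with Xbp1 shRNA and 301 in the direct comparison, and 1643 and 1834 against control.

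Without 1 array the counts ranged from 6352 to 7143 (v-Hras), 1986 to 3145 (Ire1a shRNA), 153 to 549 (Xbp1 shRNA), 2694 to 3988 (direct), 6331 to 7292 and 6537 to 7056 (against control), 29 to 151 (shared), 1129 to 1572 (Ire1a opposite to v-Hras) and 59 to 242 (Xbp1 opposite to v-Hras). Of the 463 genes, 145 were still called without v-Hras scrambled replicate 2. Without any 1 v-Hras scrambled array limma called no gene lower with Xbp1 shRNA in the mitosis, DNA replication, dermal fibroblast, ER chaperone, amino acid response and suprabasal lists. Over the fits without 1 array, list counts that also moved by over 1.5 times included, with Ire1a shRNA, the falls of MAPK output (5 to 3) and cytokine genes (9 to 4) and the rises of heat shock (4 to 2), metalloproteinase (4 to 2) and suprabasal genes (5 to 3), and in the direct comparison the higher Id genes and SMAD1/5 targets (6 to 3), glycolysis (4 to 2) and basal genes (3 to 1). The report names others, and counts of 1 or 2 with Ire1a shRNA reached 0 or 1 for basal, cholesterol, glycolysis and heat shock genes.

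Lists called numbered 19, 13, 14 and 15 in the first 4 comparisons, and 18 to 19, 11 to 13, 13 to 16 and 14 to 15 without 1 array. With an estimated correlation 12, 5, 8 and 4 were called. Fry, which asks only whether a list moved, called 20 with Ire1a shRNA and 26 in the direct comparison.

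Of 446 named gene values per alternative, 27 calls were lost with all probe sets, 9 on median centring, 10 with cyclic loess, 10 with a further quantile normalization, 9 with the mean of probe sets, 45 with 6 arrays, 31 with the block and 1 with the variance trend. Calls were gained for 10 with the variance trend, 7 with the offset, 4 with array weights and 1 each on median centring and a further quantile normalization, and for 7 of 425 without dim genes. Over the fits without 1 array 399 of 5352 were lost and 5 gained.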

Other observations

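All gene families in this part were chosen after their values were seen, and no test of a hypothesis is added.

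Late cornified envelope genes of the Lce3 cluster were called together. All 6 measured rose with v-Hras (median log2 difference 4.63, 3.91 to 4.68 under the other scalings) and all 6 fell with Ire1a shRNA (median -1.53), while none was called by limma with Xbp1 shRNA (median 0.03, whose sign changed on centring each array on its median). In the direct comparison all 6 were lower with Ire1a shRNA (median -1.54). Of the neighbouring Sprr2 genes 7 of 8 rose with v-Hras (median 3.39, 2.46 to 3.45 under the other scalings) and 6 fell with Ire1a shRNA (median -1.46). Control means of Lce3a, Lce3b, Sprr2d, Sprr2e, Sprr2f, Sprr2j-ps and Sprr2k lay below the lowest array median, as did the Ire1a shRNA mean of Sprr2f, so the sizes of these rises and of that fall, and the v-Hras medians that include them, are not established. Sprr2b went the other way in each, at -2.02 and 1.00. The Sprr2 genes had a median of -0.38 with Xbp1 shRNA (-0.43 to -0.34 under the other scalings), with Sprr2e alone called lower (-0.43, limma adjusted p = 0.0341). That call was lost without v-Hras scrambled replicate 1, 2 or 3 (0.115, 0.121 and 0.0984), Ire1a shRNA replicate 1 or 3 (0.0554 and 0.0557) or Xbp1 shRNA replicate 1, 2 or 3 (0.119, 0.0564 and 0.0807).

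Aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, moved mostly with the amino acid response list, which holds some of them. Of 15 measured 14 rose with v-Hras (median 0.75) and 10 fell with Ire1a shRNA (median -0.54), with Nars at -1.26. Limma called none with Xbp1 shRNA (median -0.07). Qars was called the other way with v-Hras (-0.23, limma adjusted p = 0.039). Among the fits that left out 1 array, that call held only in those without control replicate 3 or v-Hras scrambled replicate 1. Without control replicate 1 or 2 the adjusted p was 0.0926 and 0.115, without v-Hras scrambled replicate 2 or 3 0.0927 and 0.128, without Ire1a shRNA replicate 1, 2 or 3 0.0558, 0.0554 and 0.0524, and without Xbp1 shRNA replicate 1, 2 or 3 0.0536, 0.0528 and 0.051. Kars was called the other way with Ire1a shRNA (0.25, limma adjusted p = 0.0357), a call lost without v-Hras scrambled replicate 1, 2 or 3 (0.0893, 0.107 and 0.0948), Ire1a shRNA replicate 1, 2 or 3 (0.1, 0.066 and 0.124) or Xbp1 shRNA replicate 1 or 2 (0.0533 and 0.0517). Centring each array on its median ended the Qars call and cyclic loess the Kars call.

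Other families were mixed. Of 42 beta-defensin genes 4 rose with v-Hras, Defb14 by 5.31 from a control mean below the lowest array median, a size not established, and 4 fell, with Defb1 at -3.56 (median -0.11). Of 16 S100a genes 8 rose, among them S100a8, a subunit of calprotectin, by 2.26, and 3 fell, with S100a4 at -1.02. S100a8 was called in opposite directions in the knockdowns, at -0.76 with Ire1a shRNA and 0.82 with Xbp1 shRNA, and its direct difference of -1.58 follows from those values.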
